A study of Mus musculus with 6 samples.

How the data were processed

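The data are 6 Affymetrix mouse expression arrays of primary hepatocytes, the parenchymal cells of the liver. Hepatocytes came from wild-type mice and from Alb/AEG-1 mice, a transgenic line that overexpresses AEG-1 (astrocyte elevated gene 1, gene symbol Mtdh) in hepatocytes. The labels give 3 arrays for each genotype, a mixed B6/CBA strain, no treatment, and culture for 24 h on collagen. Total RNA was converted to biotinylated cRNA for hybridisation, per the labels' protocols.

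The deposited values are log2 expression values per probe set, which the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA subtracts background, equalises the distribution of values between arrays and summarises the probes of each probe set. The version, and whether all 6 arrays were normalized together, are not given in the sources used here. Equalising distributions removes any change shared by most genes, so the values show changes relative to the rest of the transcriptome, and it compresses differences at very low and very high signal. Arrays have no read depth, and the number of arrays limits the precision.

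The table held 22690 probe sets, of which 64 were controls. Of the others, 20380 carried 1 gene symbol in the platform annotation, 691 carried several and 1555 carried none. Gene identifiers of 20351 probe sets with 1 symbol matched the mouse reference gene table of assembly GRCm38.p6, and no symbol differed (0 of these). That table was used for names and gene order, and no coordinates were taken from it. Each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 12393 genes. Probe sets with several symbols or none stayed out of the gene comparison.

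Differences between the genotypes were tested for each gene with limma (version 3.58.1 in R 4.3.3, tables handled with the data.table package, version 1.17.8), using lmFit and eBayes on the deposited log2 values. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. All differences are transgenic minus wild type, and all limma tests are two-sided. Gene lists for liver pathways, nuclear receptor targets, other cell types of the liver, sex and strain were written from general knowledge before the data were examined. Of 57 lists, 56 had at least 3 measured members and were tested with camera at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists. Of 1164 list members, 1009 were measured, and lists share genes. Camera was repeated with a correlation estimated for each list, and fry was run on the same values. The 3' to 5' signal difference of the control probe sets for Gapdh and Actb was compared by two-sided exact permutation tests, which cannot give a p under 0.1 with 3 arrays against 3.

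Genes to be named were fixed by rule before the data were examined. They are Mtdh, the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups do not overlap (skipping predicted and unnamed clone genes), and up to 4 members with the smallest p of each list described. Genes outside the rule are given as chosen after their values were seen.

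The procedure was tested on simulated data with the means and spread of these 12393 genes. Of 200 genes changed by 0.5 on the log2 scale it recovered 96.5%, with 12 false calls, and of 200 changed by 1 it recovered 100%, with 14 false calls. With no gene changed it made 0 calls. Camera called the simulated list shifted by 0.5 and, with no change, called 0 of 56 lists. The genes were simulated independently of each other, so this does not test false list calls among correlated genes.

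Alternatives covered how a gene is represented, a filter on dim genes, further scaling, the variance prior, array weights, leaving out each array, a block for the replicate number, testing every probe set, thresholds on fold and p, a model without moderation and other tests for lists. The labels call the samples biological replicates without saying whether they are separate animals or cultures, so p-values measure the spread between these samples. No batch, slide or date label was used here.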

Results

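Gene expression was measured on 6 arrays, 3 of hepatocytes from AEG-1 transgenic mice and 3 of wild-type hepatocytes, all 24 h after plating. The arrays had similar medians, from 5.61 to 5.64 on the log2 scale. The genotypes separated on the first principal component, which carried 65.0% of the variance, while the next component carried 11.1%. Correlations across genes ranged from 0.9976 to 0.9982 between arrays of one genotype and from 0.9933 to 0.9940 between genotypes. The median standard deviation of a gene was 0.076 in the transgenic and 0.084 in the wild-type arrays.

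The brightest probe set of Mtdh, the gene that encodes AEG-1, was 3.79-fold higher in transgenic hepatocytes, at 10.64 ± 0.21 against 8.72 ± 0.07 log2 units (SD, n = 3 per genotype). The difference was 1.92 (SE 0.10), with a limma adjusted p of 2.04e-05. The increase was carried by 1 of the 6 Mtdh probe sets on the array, 1455129_at. The other 5 gave differences from -0.27 to 0.24, none of which passed the threshold, and the closest had an adjusted p of 0.0510 when all probe sets were tested. With the mean of the 6 probe sets in place of the brightest, the difference was 0.28, with an adjusted p of 0.0116. The species of the transgene sequence, and so which of these probe sets can detect it, is not given in the sources used here.

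The comparison of genotypes asks which genes differ in hepatocytes that overexpress AEG-1. By camera at the preset correlation, the fixed lists of interferon response, acute phase and complement genes were called higher in transgenic cells, with 23 of 29, 8 of 25 and 7 of 21 members risen. Those calls were lost with an estimated correlation (adjusted p = 0.0824, 0.149 and 0.149). The lists of PPARA targets, de novo lipogenesis and cholesterol synthesis were called lower, with 14 of 31, 11 of 21 and 9 of 19 members fallen. Those calls were lost too (adjusted p = 0.149, 0.367 and 0.243 with an estimated correlation). Among the genes named by rule, each at its brightest probe set, the increases ran up to 6.34-fold for Cyp46a1, the cholesterol 24-hydroxylase, and the decreases up to 20.0-fold for Ctse, the aspartic protease cathepsin E, whose transgenic level of 4.62 lies under the array median. In all, 1967 of 12393 genes changed (15.9%), 846 higher and 1121 lower, by limma with Benjamini-Hochberg adjustment. Of these, 170 were higher and 188 lower by at least 1.5-fold, and 49 and 44 by at least 2-fold. The median size of a change was 0.36. The arrays of the genotypes did not overlap for 4272 genes (34.5%), where chance gives 10%. Without transgenic replicate 1, 1267 genes passed, and without transgenic replicate 3 the genes lower in transgenic cells numbered 741. Of 868 changed genes with several probe sets, 350 had another probe set called the same way and 20 had one called the opposite way.

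The largest increases involved genes with varied roles. Cyp46a1 rose by 2.67 (SE 0.15, adjusted p = 2.34e-05) and Cyp2c23, an arachidonic acid epoxygenase, by 2.52 (SE 0.06, adjusted p = 7.40e-07). The metallothionein gene Mt4 rose by 2.42 (SE 0.06), the epidermal envelope gene Lce1d by 2.35 (SE 0.08), the class Ib histocompatibility gene H2-Q5 by 2.35 (SE 0.11) and the germ cell factor Dppa3 by 2.28 (SE 0.07). Chemokine genes were among them, with Ccl3 at 7.02 ± 0.06 against 5.14 ± 0.10 and Cxcl9 at 11.70 ± 0.03 against 9.83 ± 0.04 (SD, n = 3), differences of 1.89 and 1.87. Ppp1r3c, which targets a protein phosphatase to glycogen, rose by 1.89 and the peptide transporter gene Slc15a2 by 1.91. Slc15a2 has a second probe set on the array, which did not pass the threshold, and the mean over both gave 1.04. Tmsb10, an actin-binding thymosin, rose by 1.93, but without probe sets that match several transcripts the difference was 0.09 (adjusted p = 0.472). The Lce1d and Cyp2c23 values rest on probe sets of that kind alone.

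Among the largest decreases, Ctse at its brightest probe set fell from 8.94 ± 0.19 to 4.62 ± 0.58 (SD, n = 3), a difference of -4.32 (SE 0.25, adjusted p = 3.26e-05). Only 1 of its 2 probe sets passed as lower, and the mean over both gave -2.09. Lgals1, which encodes a galectin, was 14.0-fold lower, with a difference of -3.80 (SE 0.08, adjusted p = 7.40e-07) and both of its probe sets past the threshold. The fatty acid omega-hydroxylase gene Cyp4a14 fell by 3.20 (SE 0.12), the lipid droplet enzyme gene Hsd17b13 fell by 2.77 (SE 0.17) and the fatty acid transporter gene Cd36 fell by 2.51 (SE 0.11). Pparg, a nuclear receptor of fat storage, fell from 8.09 ± 0.02 to 6.08 ± 0.13, a 4.03-fold decrease (adjusted p = 2.58e-06). Fitm1, which acts in lipid droplet formation, fell by 1.92, and Mogat1, a monoacylglycerol acyltransferase, fell by 1.87. Pltp, the phospholipid transfer protein, and Angptl4, an inhibitor of lipoprotein lipase, each fell by 1.92, and the other probe set of Angptl4 gave -0.69 (adjusted p = 0.0255). Cyp2c39 fell by 2.50 and the G protein subunit gene Gnai1 fell by 1.93. Without probe sets that match several transcripts, Gnai1 gave -0.81. In transgenic cells Ctse, Hsd17b13, Gnai1 and Mogat1, and in wild-type cells H2-Q5, Dppa3, Slc15a2 and Ccl3, lay under the array median of 5.63, where signal is nearer to background and a fold is less certain.

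**Figure D1:**
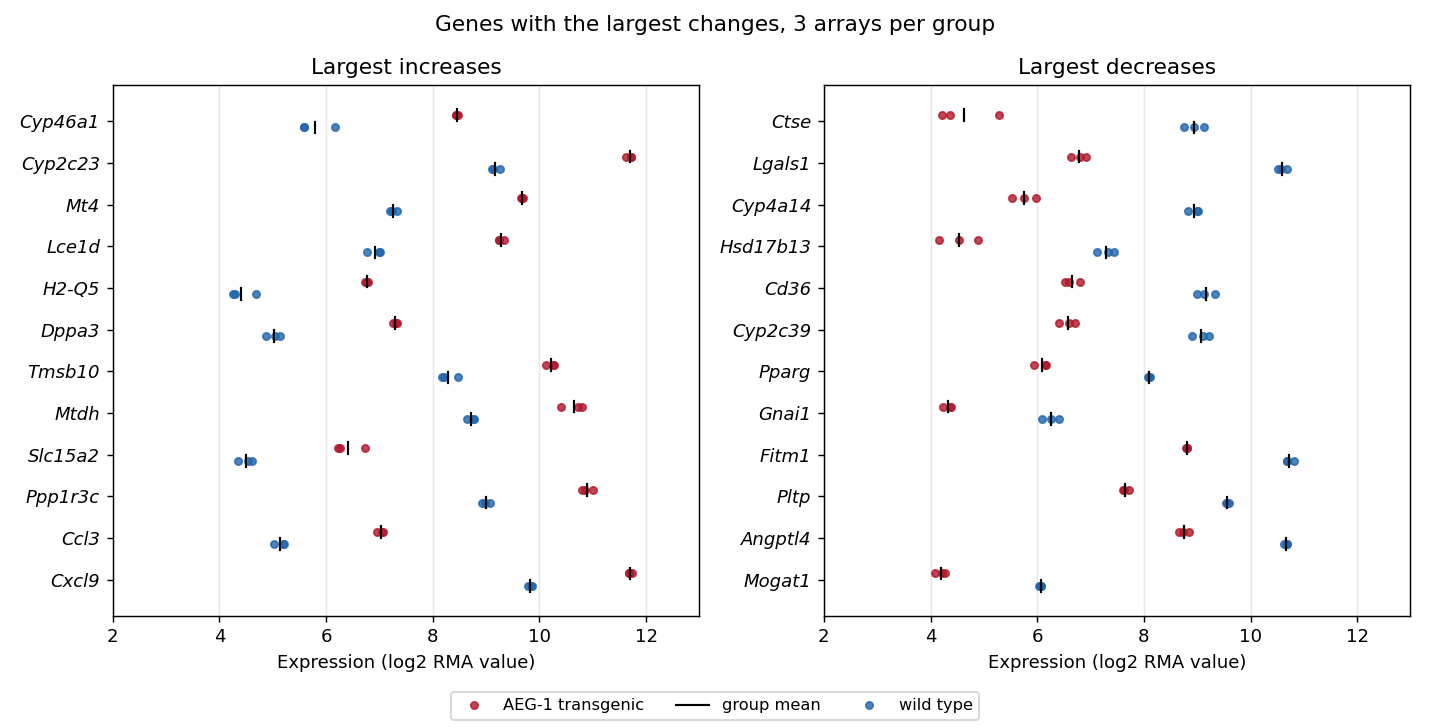
Log2 RMA values of the 12 largest increases (left) and the 12 largest decreases (right) on each array, with points for the 3 arrays per genotype and vertical ticks for the group means. In each gene the transgenic and wild-type arrays do not overlap, as for Ctse, at 4.62 in transgenic against 8.94 in wild-type cells.

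Interferon response genes were higher as a group. Of 29 measured members, 23 rose, 1 fell and 5 did not pass, with 26 higher and 2 lower when adjusted over the list alone. The list median was 0.59 and camera gave an adjusted p of 2.06e-18 (adjusted p = 0.0824 with an estimated correlation). Usp18, a brake on interferon signalling, rose 3.19-fold (1.67, SE 0.06), Ifit1 by 1.55, Ifit3 by 1.51 and the antiviral gene Rsad2 by 1.25 (SE 0.06). Bst2, named after its value was seen, was the member that fell, by 0.26. Targets of NF-kB and inflammatory mediators were also higher, with 12 of 33 members risen and 0 fallen, or 14 and 0 adjusted over the list alone. Camera gave an adjusted p of 0.000208 for that list (adjusted p = 0.149 with an estimated correlation). Kupffer cell markers were also called higher by camera, with 4 of 25 risen and 1, Cd14, fallen (adjusted p = 0.369 with an estimated correlation). Il6, at 4.22 in wild-type cells and so under the array median of 5.63, rose by 1.80 (SE 0.13), Cxcl2 by 0.96 and Cxcl10 by 0.92.

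Acute phase and complement genes, which encode secreted liver proteins, had list medians of 0.14 and 0.18. Among 25 acute phase genes 8 rose and 0 fell, or 10 and 0 adjusted over the list alone, with Saa3 up by 0.78 (SE 0.07), Serpina3n by 0.57 and A2m by 0.55 (camera adjusted p = 1.20e-05, and adjusted p = 0.149 with an estimated correlation). Among 21 complement genes 7 rose and 0 fell, or 12 and 0 adjusted over the list alone, with C8b up by 0.61 and C2 by 0.57 (camera adjusted p = 0.000108, and adjusted p = 0.149 with an estimated correlation). The complement list shares C1qa, C1qb and C1qc with the macrophage markers, and of these C1qc is among the risen, by 0.35. Of 27 coagulation genes 5 rose and 1 fell, or 9 and 1 adjusted over the list alone. Camera called that list higher, at an adjusted p of 0.00524 (adjusted p = 0.367 with an estimated correlation). F3, tissue factor, rose by 0.51 (SE 0.09), while F12, the contact factor gene, fell by 0.75 (SE 0.05).

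PPARA target genes, a list that holds fatty acid oxidation genes and others such as Cd36, Angptl4 and Vnn1, were lower. Of 31 measured members 14 fell, 0 rose and 17 did not pass, with 16 lower when adjusted over the list alone. The median was -0.20 and camera gave an adjusted p of 7.01e-09 (adjusted p = 0.149 with an estimated correlation). Beside Cyp4a14, Cd36 and Angptl4, the pantetheinase gene Vnn1 fell 2.43-fold (-1.28, SE 0.06). In de novo lipogenesis 11 of 21 genes fell and 1 rose, or 14 and 2 adjusted over the list alone (camera adjusted p = 1.20e-05, and adjusted p = 0.367 with an estimated correlation). Pklr, the liver pyruvate kinase, fell by 0.71 (SE 0.06). Malic enzyme Me1 (-0.57), the lipogenic regulator Srebf1 (-0.52) and the desaturase Scd1 (-0.45) also fell, Scd1 with -0.28 as the mean of its probe sets. In cholesterol synthesis 9 of 19 genes fell and 2 rose, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.000140, and adjusted p = 0.243 with an estimated correlation). Hmgcs1 (-0.73, SE 0.06), Nsdhl (-0.56) and Dhcr7 (-0.45) fell, while the sterol carrier gene Stard4 rose by 0.50, or by 0.28 as the mean of its probe sets.

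Targets of the receptors that pair with RXR moved unequally, though the differences between lists were not tested. LXR targets were called lower, with 7 of 19 fallen and 2 risen, both counts unchanged when adjusted over the list alone (camera adjusted p = 0.0226, and adjusted p = 0.434 with an estimated correlation). Pltp and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell the most in that list, Cyp7a1 with a difference of -1.05 (SE 0.07). The LXR list passed under 12 of 16 settings, with a highest adjusted p of 0.125, on ranks. Thyroid hormone receptor targets did not pass (camera adjusted p = 0.0785), with 6 of 17 fallen and 3 risen, or 8 and 3 adjusted over the list alone. That list passed as lower with a variance trend (adjusted p = 0.0334), without transgenic replicate 3 (adjusted p = 0.0366) and by fry (adjusted p = 0.00189). In it Dio1, the deiodinase that activates thyroid hormone, fell to 5.28, under the array median (-1.83, SE 0.09), and G6pc, a glucose phosphatase, fell by 0.86. FXR targets went both ways, with 3 of 19 risen and 5 fallen, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.808, and adjusted p = 0.00894 by fry). The repressor gene Nr0b2 rose by 0.87 (SE 0.06) and the transporter gene Slco1a4 fell by 0.88, and the list's median was positive while its mean and camera were negative. The receptor target lists do not mark whether a receptor raises or lowers a member, so the counts and camera directions do not measure receptor activity. RAR targets did not pass (camera adjusted p = 0.995), with 2 of 15 risen and 2 fallen, the same counts adjusted over the list alone. Rarb, at 4.93 in wild-type cells and so at low signal, rose by 1.00 (SE 0.11) and Cyp26a1, which degrades retinoic acid, by 0.75, while the corepressor gene Nrip1 fell by 0.87. In retinoid handling 9 of 26 genes fell and 1 rose, or 11 and 2 adjusted over the list alone, with Rdh16 at -1.10 and Aldh1a7 at -0.58 (camera adjusted p = 0.00205, and adjusted p = 0.149 with an estimated correlation).

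**Figure D2:**
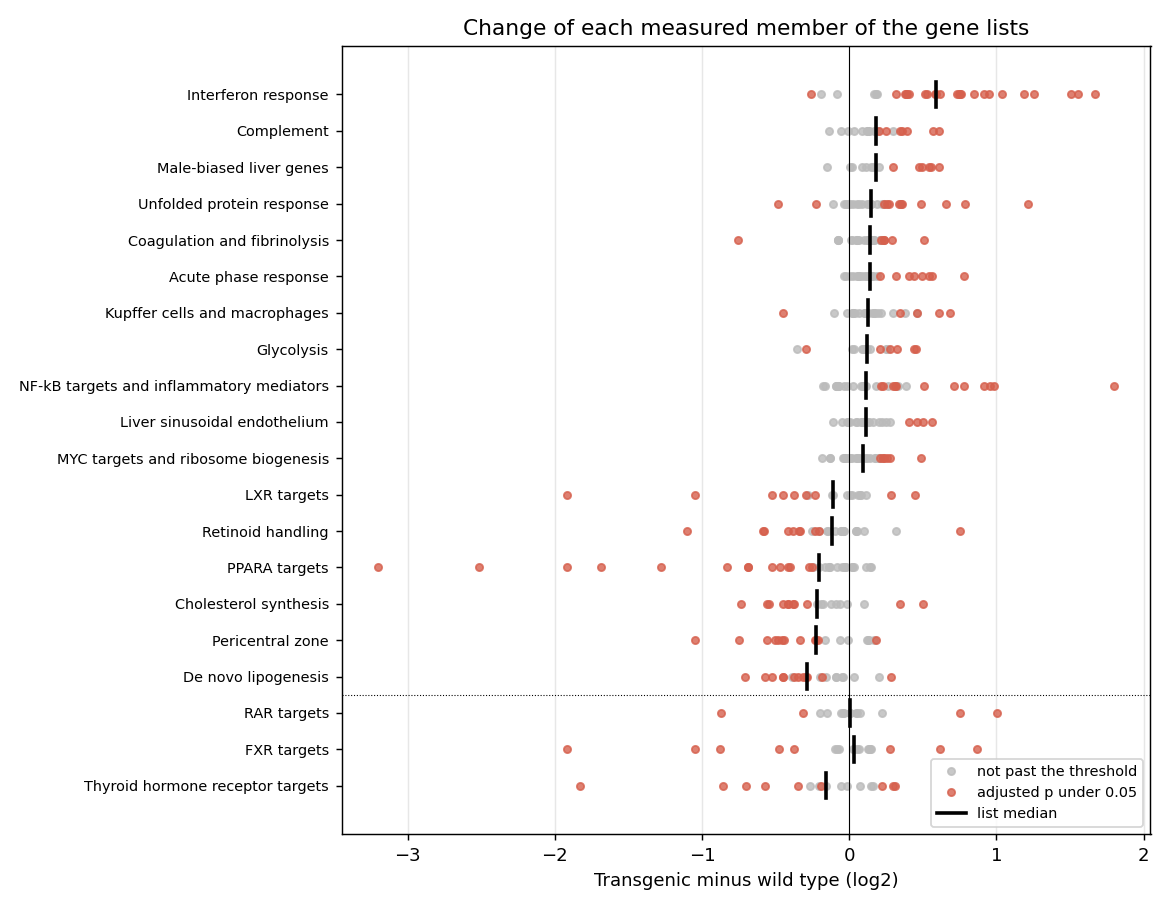
Transgenic minus wild-type log2 difference of each measured member of the 17 lists past the camera threshold (above the dotted line) and of 3 further receptor target lists, with points coloured by whether the gene passed an adjusted p of 0.05 and black ticks for list medians. The interferon response list has the highest median, 0.59, and de novo lipogenesis the lowest of the 17, -0.28.

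Several other lists were called by camera at the preset correlation, and which cells carry these changes was not tested. Unfolded protein response genes were higher, with 10 of 29 risen and 2 fallen, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.000137, and adjusted p = 0.149 with an estimated correlation). Asns, asparagine synthetase, rose 2.32-fold (1.21, SE 0.09), and the secreted chaperone-related genes Manf and Creld2 rose by 0.79 and 0.66. Genes of the pericentral zone, the hepatocytes around the central vein, were lower, with 11 of 19 fallen and 1 risen, or 12 and 1 adjusted over the list alone. Glutamine synthetase Glul fell by 0.50 and Oat fell by 0.56 (camera adjusted p = 0.000649, and adjusted p = 0.332 with an estimated correlation). Of 17 glycolysis genes 5 rose and 1 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0145, and adjusted p = 0.223 with an estimated correlation), led by Aldoa at 0.44 and Pfkfb3 at 0.46. MYC targets and ribosome biogenesis genes gave 6 of 28 risen and 0 fallen, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.0282, and adjusted p = 0.332 with an estimated correlation). The glycolysis list missed the threshold without probe sets that match several transcripts (adjusted p = 0.0667) and the MYC list without transgenic replicate 1 (adjusted p = 0.0856). Male-biased liver genes gave 6 of 14 risen and 0 fallen, the same adjusted over the list alone, among them Elovl3 at 0.55 and Cyp7b1 at 0.50 (camera adjusted p = 0.000309, and adjusted p = 0.149 with an estimated correlation). Another of the risen, C8b at 0.61, is also on the complement list.

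Lists of cell cycle, invasion and fetal liver genes did not pass camera at the preset correlation. Of 39 cell cycle genes 1 rose and 4 fell, or 1 and 6 adjusted over the list alone (camera adjusted p = 0.0855). The list passed as lower with the mean of a gene's probe sets (adjusted p = 0.0391) and by fry (adjusted p = 0.0321). Among its members were Pcna at -0.32 and Ccne1 at 0.37. Of 30 angiogenesis and invasion genes 4 rose and 3 fell, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.444), with Mmp13, near background at 3.75 against 2.88, up by 0.87 and Vegfa by 0.39. Of 23 fetal liver and liver tumour genes 2 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.193), and the list passed by fry (adjusted p = 0.0351). The risen were Tff3, 3.02-fold (1.59, SE 0.07), and Epcam, by 1.52 (SE 0.10) from a low wild-type level of 4.53.

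Markers of other liver cell types were measured beside these groups. Kupffer cell and macrophage markers were called higher, with 4 of 25 risen and 1 fallen, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00634, and adjusted p = 0.369 with an estimated correlation). Ptprc rose by 0.61 and Mrc1 by 0.46, while Cd14 fell by 0.45. Sinusoidal endothelium markers gave 4 of 22 risen and 0 fallen, the same adjusted over the list alone, with Bmp2 up by 0.56 (camera adjusted p = 0.00979, and adjusted p = 0.497 with an estimated correlation). The endothelial list missed the threshold without transgenic replicate 3 (adjusted p = 0.0592), without wild-type replicate 2 (adjusted p = 0.0814) and by fry (adjusted p = 0.0821). Neutrophil markers had 0 of 13 changed (camera adjusted p = 0.657), T and NK cell markers 1 of 16, Ccl5, up by 0.99 (adjusted p = 0.176), and stellate cell markers 1 of 21, Lum, up by 0.20, a call lost under 10 settings (list adjusted p = 0.0785, and 0.0322 without transgenic replicate 2). In the list of B cells, 2 of 9 fell, Ighm at -1.80 and Ly6d at -0.54 (camera adjusted p = 0.176, and adjusted p = 0.00244 by fry), although the Ighm probe sets disagreed, with a mean of -0.30. Cholangiocyte markers gave 1 risen, Epcam, and 1 fallen, Anxa5, of 15 (adjusted p = 0.384, and 0.0437 by fry). The Anxa5 call was lost under 6 settings, with adjusted p from 0.0502 to 0.0831. The counts were 1 risen, Car1, and 2 fallen, Car2 and Klf1, of 11 erythroid markers (adjusted p = 0.755), 0 risen and 1 fallen, Cidec, of 9 mesothelial and adipose markers (adjusted p = 0.788) and 0 changed of 9 pancreatic acinar markers (adjusted p = 0.893). Hepatocyte identity genes gave 3 risen and 6 fallen of 26 (adjusted p = 0.702). Female-biased liver genes gave 0 risen and 2 fallen, Cyp4a14 and Acot3, of 14 (adjusted p = 0.0737). Both fallen genes are also members of the PPARA target list. The female-biased list passed as lower with the mean of a gene's probe sets (adjusted p = 0.0391), after quantile normalization (0.0347), without transgenic replicate 2 (0.0402) and by fry (0.00642). None of the 6 measured X-inactivation and Y-linked genes changed (0 by limma, 2 at an unadjusted p under 0.05), and Y-linked Eif2s3y was at 8.82 ± 0.04 against 8.94 ± 0.10. Uty passed limma with the replicate block (-0.41, adjusted p = 0.0290) and Tsix without wild-type replicate 3 (-0.27, adjusted p = 0.0454), both genes at levels under the array median. The 3' to 5' difference of Actb was 0.875 ± 0.044 against 0.895 ± 0.032 (exact permutation p = 0.5) and that of Gapdh 0.103 ± 0.009 against 0.074 ± 0.058 (exact permutation p = 0.6), where 0.1 is the smallest p possible.

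With estimated correlations, 0 of 56 lists passed after adjustment and 10 had an unadjusted p under 0.05, while 37 passed by fry, which tests a list's own movement and makes no comparison with other genes. The list calls rest on camera run with the preset correlation between genes. The estimate was not always the higher value: for the unfolded protein response list it was -0.0080, under the preset 0.01. The unadjusted camera p of that list still rose from 1.47e-05 to 0.00803. Estimates were also under 0.01 for the retinoid handling (-0.019), glycolysis (-0.013), male-biased (-0.0065) and NF-kB (0.0023) lists, whose calls were lost too. A higher correlation between genes alone therefore does not account for the lost calls. A call lost with an estimated correlation is thus not by itself a sign that the members of a list move together.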

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

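Tests of the interferon, lipid and strain patterns below were chosen after the result was seen. Exceptions are the sign test on neighbouring genes, the counts over other splits of the samples, and the camera and fry tests.

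Probe sets that carry no gene symbol were outside the gene comparison and also changed with genotype. When all probe sets were tested with limma, 134 of 1555 without a symbol passed the threshold, as did 59 of 691 with several symbols. The largest increase without a symbol was 1417185_at, at 9.65 against 5.96, a difference of 3.69 (SE 0.10, adjusted p = 6.58e-07), and the largest decrease was 1417867_at, with a difference of -1.77 (SE 0.12, adjusted p = 8.31e-05).

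Over the 10 splits of the 6 samples into 3 and 3, the real one gave 1967 changed genes and the highest of the others 0, so 1 split reached the real count. For gene lists the real split gave 17 and the highest of the others 9, again 1 split. With 10 splits the share cannot fall under 0.05. Each of the other splits put arrays of both genotypes on each side. The difference between genotypes then added to the spread within each side, which lowers the number of genes called. Part of that difference also stayed between the sides, so the list counts of those splits still carry it. The splits therefore cannot decide how many genes or lists would be called without a difference between genotypes.

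The interferon genes were higher together with some macrophage markers, so a larger share of immune cells in the transgenic cultures is a candidate explanation. The Marco call named next was lost without transgenic replicate 1, wild-type replicate 2 or wild-type replicate 3 (adjusted p = 0.0512, 0.0511 and 0.0600 by limma). Among all 25 Kupffer cell and macrophage markers, at every level, Marco (0.69), Ptprc (0.61), Mrc1 (0.46) and C1qc (0.35) rose, Cd14 fell by 0.45, and others did not pass, such as Slc15a3 (0.46), Fcer1g (0.38), Lyz2 (0.10), Csf1r (-0.10) and Cd5l (0.02). Their median was 0.12, and the interferon median lay above it by 0.47 (bootstrap 95% interval 0.24 to 0.67), by 0.44 (0.18 to 0.66) with the 19 above the array median or past the threshold, by 0.52 (0.29 to 0.72) with all 63 immune markers, and by 0.53 (0.30 to 0.73) with the 18 above the array median in no inflammatory list, a choice that leaves out Marco, Ptprc, C1qc and the T cell marker Ccl5, which all rose. These intervals come from resampling genes, not arrays, so they carry no spread between cultures. Many of the markers also lay near or under the array median, where differences can be compressed. The values show a larger median rise of the interferon genes than of the markers. They do not settle how much immune cell number contributes. Activation of the immune cells present, a difference between cultures or batches, and an effect of AEG-1 in hepatocytes stay open and were not tested.

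A lower share or poorer differentiation of hepatocytes could lower lipid genes. A log2 level of 13, set by hand, was taken as the start of the saturated range, although Scd1 above it still passed (13.62 in transgenic against 14.07). Over all 58 PPARA, lipogenesis and cholesterol genes between the array median and that level the median was -0.25. The 12 hepatocyte identity genes used in that range, of 26 measured, lay 0.21 above them. The bootstrap 95% interval of that difference, from resampling genes and not arrays, was -0.10 to 0.40. It includes 0, so the test does not decide and the explanation stays open. An effect of AEG-1 and unlabelled differences in isolation or culture stay open too.

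In a mixed strain, alleles that differ between the groups might add to the changed genes. Of 12 measured genes known to differ between inbred strains 6 changed, where 1.82% of 10000 expression-matched random lists had as many. They include Nnt (0.74), Glo1 (0.48), Akr1e1 (0.70) and Trim12a (-0.55), the last at a mean level of 3.61, under the array median. By camera that list did not pass (adjusted p = 0.139). It passed as higher by fry (adjusted p = 0.00119) and by camera with dim genes left out (adjusted p = 0.0297). Neighbouring genes were taken as unrelated when their symbols differed before the first digit or hyphen, so relatives with different names can remain among the pairs. Among neighbouring unrelated genes, 346 pairs both changed against a mean of 309 and an upper 95% bound of 338 in 1000 expression-matched permutations, as differing strain segments would give. Of these pairs, 209 moved the same way, above the mean of 176 and the upper bound of 193 under permuted signs, as shared regulation of neighbours would give. The 137 pairs that moved in opposite directions lay below the mean of 151 but within the 95% range, 131 to 173, of the expression-matched permutations, so strain segments stay open, as do strain alleles at single genes, which this count does not test.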

How the results depend on the processing

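The alternatives were chosen before the data were examined. No gene or list past the threshold in either setting turned its test's direction, while 1 value for a named gene and 23 for lists did so without passing in either. The antigen presentation list, whose mean of -0.0093 differs in sign from its camera direction (adjusted p = 0.893), passed as higher without probe sets that match several transcripts (mean 0.13, adjusted p = 0.0457), and the cause was not tested. Of 137 named genes besides Mtdh, 108 passed the threshold and 94 of these passed with each array left out in turn. Under the other settings 1792 of 1874 values for named genes kept their call, 66 lost it and 16 gained it. For lists 883 of 948 kept it. Of the 17 lists called, 13 passed under all 16 settings other than the estimated correlation, and the LXR list passed under 12. A fold of at least 1.5 left 358 genes (170 higher, 188 lower) and a fold of at least 2 left 93 (49 and 44), by construction. Without moderation of the variance 1271 genes passed (560 and 711). Leaving out 1 array gave 1267 to 1700 changed genes, 540 to 739 higher and 727 to 961 lower, with fewer arrays. It gave 16 to 20 lists and 1 to 3 lists of other cell types. The estimated correlation left 0 lists, 0 of them of other cell types, and fry called 37. The share of variance on the first component was 80.1% with dim genes left out and 66.5% to 69.9% with an array left out. The Actb 3' to 5' difference between genotypes was -0.0641 after quantile normalization and -0.0435 to -0.00039 with an array left out. The cause was not tested. With the replicate block 1505 genes passed (640 and 865), of which 1436 are shared. The deviations of same-numbered samples correlated at -0.010, -0.0097 and 0.104, against -0.069 to 0.069 for differently numbered ones. Not every pair was over 0.1, so the numbers were not taken to pair the samples, though the third pair stands above that range. Signal over background limits the genes at low levels: with those left out, 2357 of 7014 genes passed.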

Other observations

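The tests in this part were chosen after the data were seen. Gene families were grouped by the stem of their symbols. By a hypergeometric test, 4 families with at least 8 measured members held more changed genes than random draws from all genes would give. These passed after Benjamini-Hochberg adjustment over 470 tests. The test did not match for expression level and treated the members of a family as independent, so its p-values may be too small. Chemokines named Cxcl had 6 of 12 members higher and 0 lower (hypergeometric adjusted p = 0.0162), with Cxcl11 up by 0.57 beside Cxcl9, Cxcl10 and Cxcl2. Serpina genes, secreted protease inhibitors and relatives, had 5 of 8 higher (adjusted p = 0.0162), led by Serpina12 at 1.81. Interferon-inducible genes named Ifi had 5 of 9 higher and 1 lower (adjusted p = 0.0229), with Ifi209 up by 1.17 and Ifi202b down, at -1.77. Peroxisome biogenesis genes named Pex had 6 of 12 lower and 0 higher (adjusted p = 0.0364), the largest being Pex11a at -0.68 and Pex26 at -0.51.

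Of 42 measured nuclear receptor genes, 8 were lower and 3 higher, where 9.05% of all genes were lower (two-sided Fisher's exact p = 0.0508, not past 0.05). Beside Pparg, the lower ones included Ppara at -0.77 (SE 0.08, adjusted p = 0.000748), the FXR gene Nr1h4 at -0.40, the xenobiotic receptor genes Nr1i2 at -0.41 and Nr1i3 at -0.36, and Rxra at -0.38 (SE 0.06, adjusted p = 0.00610). The higher ones were Rarb, Nr0b2 and Nr2c1.

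Around Nnt, 5 of 11 genes in gene order changed, and the 4 next to it on one side, Paip1 (-0.37), 4833420G17Rik (-0.71), 3110070M22Rik (-0.55) and Tmem267 (-1.36), were lower while Nnt was higher. Paip1 has another probe set called the opposite way, at 0.47 (SE 0.10, adjusted p = 0.0177). For H2-D1 the probe sets past the threshold ran from -0.58 to 4.52, and H2-Q5, among the largest increases, rests on 1 probe set. Whether strain alleles add to the differences at these histocompatibility genes was not tested.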
